A study of Homo sapiens with 12 samples.

How the data were processed

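RNA was measured by sequencing in 12 libraries of cells that the labels name as neutrophils induced from HL-60, a human promyelocytic leukaemia cell line. The labels place 3 libraries in each of 4 groups, all taken after 24 h: BSA at 0.05 µg/mL, which the treatment protocol names as the control, advanced glycation end products (AGEs) at 0.05 µg/mL, D-glucose at 30 mmol/L, and AGEs with D-glucose. The glucose group is not labelled as holding BSA. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

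The deposited table holds gene-level FPKM values (fragments scaled to gene length and library total), per the file headers, in 1 column per library. The submitters' processing notes name cutadapt, HISAT2 2.0.5, StringTie and STAR 2.5.2b and the genome build hg19, with no role or order. The gene annotation, the strand setting and any filter are not given in the sources used here. The table has 10465 rows with 10446 distinct symbols, and 19 symbols stand in 2 rows. In every row the highest of the 4 group means is at least 0.5001 FPKM, so genes below a group mean of 0.5 were not analysed here. FPKM sums ran from 220444 to 233854 per library. FPKM keeps no read counts, so the depth of each library is unknown and no counting intervals were computed. No pair of libraries held identical values.

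Gene symbols were matched to a GRCh38 gene annotation and name table. Its gene spans were used only to count overlapping coding genes, without regard to strand, and no coordinates are printed. GC content and length were those of the longest transcript of each gene in a separate transcript annotation, GENCODE. Of the rows, 9816 carried a current symbol, 463 matched 1 older symbol and 186 did not match. GC content and length were found for 98.9% of the genes tested.

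Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Rows were kept where FPKM was at least 1 in at least 3 libraries, which removed 714 and left 9751 genes. All 12 libraries entered 1 fit of group means in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0), with an intensity trend and robust variance moderation. The contrasts were each stimulated group against BSA, the stimulated groups against each other, and the interaction, the change from AGEs to AGEs with glucose minus the change from BSA to glucose. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05. Fold changes are given with the limma standard error.

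Before the data were examined, 38 gene lists with 871 entries were written down for neutrophil function, other blood cell types, inflammation, glucose use, stress, lipid synthesis and growth. Of these entries 196 were not in the table. The 36 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast, and 2 lists were too small. Members past the threshold were counted over all genes tested and adjusted over the list alone. Camera with a correlation estimated from the data and fry, which tests whether the members of a list move on balance in 1 direction, were the alternatives.

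Genes named in the text followed a rule set before the data were examined. In each comparison against BSA it took up to 8 called genes per direction with separated groups, or, where fewer than 3 passed in a direction, the 3 with the smallest unadjusted p, given as values. The other contrasts used up to 4. It also took 2 to 4 members with the smallest p from each list described, of which the text gives fewer, or none, for lists whose call was lost with an estimated correlation and in the contrasts between stimulated groups. It took AGER, TXNIP, ARRDC4, MPO, ELANE and PADI4 always. ELANE and PADI4 were not analysed here.

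The fit and the list tests were checked on simulated values for the 9751 genes. These were drawn independently for each gene, with no outlying library and no GC trend. For AGEs against BSA, 14% of 50 genes changed by 1.25-fold were called, 50% at 1.5-fold, 86% at 2-fold and 88% at 3-fold, with 5 false calls among 124. For glucose against BSA these shares were 18%, 42%, 76% and 96%, with 9 false calls among 125, and for AGEs with glucose 16%, 54%, 78% and 88%, with 5 among 123. Far more genes were changed here than were called in the data, so these shares may be too high for it. A list moved by 0.2 log2 for glucose against BSA was called by preset camera, with 0 other lists. With independent genes this does not test camera where genes move together.

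Fixed before the data were examined, further fits used a pseudocount of 0.1, no filter, a mean FPKM of at least 5, TMM scaling and quantile normalization, no trend and no robust step, only the groups compared, library weights, the replicate number as a block, an added 2-fold minimum and leaving out each library in turn. TMM factors lay between 0.987 and 1.016. Fits without AGEs 1 and glucose 3 were added after the data were seen. So were fits with per-library GC and length trends removed by splines with 4 degrees of freedom, and list tests under library weights and with each library left out. Gaps between the library means of a list were also measured after the data were seen. Figures were drawn from these tables.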

Results

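Gene expression was compared in HL-60-derived neutrophil-like cells kept for 24 h with BSA (0.05 µg/mL), with AGEs (0.05 µg/mL), with D-glucose (30 mmol/L) or with AGEs and glucose together. HL-60 is a promyelocytic leukaemia line that can be driven toward granulocytes, and AGEs are proteins modified by reducing sugars, which accumulate in diabetes. The series contrasts these 2 stimuli. Each group had 3 libraries with FPKM sums of 220444 to 233854, and their read depth is unknown. The log2 values of libraries correlated across genes at 0.974 to 0.988 within groups and 0.973 to 0.987 between groups.

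In the BSA libraries the cells expressed the integrin subunits ITGB2 at 195 ± 0.806 FPKM and ITGAM at 70.8 ± 4.47 FPKM (SD, n = 3). MPO, the myeloperoxidase of primary granules, stood at 110 ± 6.69 FPKM, and PRTN3, a protease of the same granules, at 1.18 ± 0.0909 FPKM. CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, was at 2199 ± 117 FPKM, and was the most abundant transcript not encoded by mitochondria over the 12 libraries. AGER, the receptor for AGEs, was at 1.65 ± 0.0925 FPKM. ITGB2, ITGAM, PRTN3 and the level of CLC in this paragraph were chosen after the values were seen. Library AGEs 1 deviated from the gene means along GC content (Spearman rho 0.70 across genes, which are not independent replicates). Its limma library weight was 0.18, and that of glucose 3 was 0.42.

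The first comparison asked what AGEs changed relative to BSA. TDG, a thymine DNA glycosylase of base excision repair, rose from 7.89 ± 0.924 to 16 ± 0.647 FPKM (SD, n = 3; log2 fold change 0.94 ± 0.08 SE, adjusted p = 0.000955). ATP2B4, a plasma membrane calcium pump, rose from 23.3 ± 2.12 to 45.1 ± 1.82 FPKM (log2 fold change 0.93 ± 0.08 SE, adjusted p = 0.000955). NDRG1, a hypoxia-inducible gene, fell from 29.9 ± 0.81 to 22.0 ± 0.532 FPKM (log2 fold change -0.42 ± 0.06 SE, adjusted p = 0.037). These 3 were all the genes that limma called among 9751 tested, while 462 had an unadjusted p under 0.05 against 488 expected by chance.

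Targets of the hypoxia factor HIF1 fell together with AGEs. Of 16 measured members 14 lay below 0, with a median log2 fold change of -0.28, and 7 were lower adjusted over the list alone against 1 over all genes tested. The list had a camera adjusted p = 2.23e-10, and 0.00279 with an estimated correlation. Besides NDRG1 they included the glucose transporter SLC2A3, at 45.1 ± 1.43 FPKM with BSA and 36.6 ± 1.05 with AGEs. They also included the glycolytic regulator PFKFB4, at 11.8 ± 0.528 and 8.97 ± 0.989, and the collagen prolyl hydroxylase subunit P4HA1, at 57.7 ± 1.5 and 47.0 ± 4.48 (SD, n = 3). AGEs 1, the library with the GC trend, was in this group. Leaving out AGEs 1 and glucose 3, the list had adjusted p = 0.0227 with an estimated correlation.

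The other lists past camera's threshold for AGEs were lost with an estimated correlation. Genes of glycolysis were lower in 15 of 23 members, with ALDOC and PFKFB4 lower adjusted over the list alone and none over all genes tested (adjusted p = 0.511 with an estimated correlation). Glucose transporters were lower in 5 of 6 (adjusted p = 0.421 with an estimated correlation), and SLC2A3 was the member lower adjusted over the list alone. Inflammatory cytokines and chemokines were lower in 14 of 19, with CXCL8, a neutrophil chemoattractant, at 121 ± 7.13 FPKM with BSA and 95.7 ± 17.1 with AGEs (SD, n = 3; adjusted p = 0.511 for the list with an estimated correlation). MYC and ribosome biogenesis genes were higher in 19 of 24 (adjusted p = 0.16 with an estimated correlation). So were nuclear-encoded oxidative phosphorylation genes in 30 of 36 (adjusted p = 0.553 with an estimated correlation) and cytosolic ribosomal proteins in 32 of 37 (adjusted p = 0.511 with an estimated correlation). Mitochondrially encoded genes were lower in 13 of 13, with adjusted p = 0.578 with an estimated correlation. In these lists no member other than those named passed adjusted over the list alone. None of the 7 lists kept its preset call in all 12 fits with 1 library left out: it held in 5 for cytokines, 8 for transporters, 2 for glycolysis, 10 for oxidative phosphorylation, 4 for mitochondrially encoded genes, 8 for MYC and 9 for ribosomal proteins. Without AGEs 1 the mean log2 difference went from -0.08 to -0.01 for cytokines and from -0.05 to -0.02 for mitochondrially encoded genes, with preset adjusted p = 0.26 and 0.165. CXCL8 was at 76.1 FPKM in AGEs 1.

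Genes with the smallest p short of the threshold were DCXR, a dicarbonyl and xylulose reductase, at 6.97 ± 0.788 FPKM with BSA and 10.5 ± 0.987 with AGEs (adjusted p = 0.145), ALDOC at 17.3 ± 0.627 and 12.2 ± 1.32 (adjusted p = 0.0992) and the steroid sulfatase STS at 7.97 ± 0.367 and 5.39 ± 0.308 (adjusted p = 0.145). AGER stood at 1.97 ± 0.261 FPKM with AGEs, MPO at 118 ± 14.5, TXNIP at 214 ± 7.07 and ARRDC4 at 4.76 ± 0.512 (adjusted p = 0.977 for each). In the limma fits that left out 1 library, TDG and ATP2B4 were called in 12 of 12 and NDRG1 in 2, those without AGEs 1 and without glucose 3. NDRG1 was not called in the fit of these 2 groups alone. With TMM scaling the calls were 2 higher and 0 lower, without NDRG1. They were mostly lower with library weights (2 higher and 8 lower), with GC and length trends removed (2 and 6) and without AGEs 1 (2 and 4). Without AGEs 1 and glucose 3 they were near even (4 and 5).

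The second comparison asked what high glucose changed relative to BSA. The glucose group is not labelled as holding BSA, so these changes may also hold the loss of BSA. TDG rose to 17.9 ± 0.371 FPKM (log2 fold change 1.09 ± 0.08 SE, adjusted p = 0.000298). CYP17A1, a steroid hydroxylase, rose from 6.36 ± 0.553 to 11.9 ± 0.335 (0.82 ± 0.09, adjusted p = 0.00695). The chaperone HSPA8 rose from 122 ± 4.57 to 157 ± 2 FPKM, the mitochondrial membrane protein STOML2 from 25.6 ± 2.31 to 39.3 ± 0.7, and ACAT2, an acetyl-CoA acetyltransferase, from 31.9 ± 1.11 to 40.8 ± 1.4 (SD, n = 3; adjusted p = 0.0253, 0.0253 and 0.0464). The BH3-only protein gene BMF fell from 13.2 ± 0.428 to 8.55 ± 0.258 FPKM (adjusted p = 0.0138). With it 4 genes of the cell surface or matrix fell: the inhibitory Fc receptor FCGR2B (13.3 ± 0.446 to 9.3 ± 0.298), thrombospondin 1 or THBS1 (12.2 ± 0.592 to 7.96 ± 0.592), CD180 (4.22 ± 0.209 to 2.66 ± 0.264) and CD300E (3.53 ± 0.334 to 2.13 ± 0.126). These last had adjusted p = 0.0253, 0.0253, 0.0253 and 0.04. The 10 calls were 5 higher and 5 lower, while 977 of 9751 genes had an unadjusted p under 0.05 against 488 expected.

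Heat shock genes, MYC and ribosome biogenesis genes and cholesterol synthesis genes rose as groups with glucose. Of 17 heat shock genes 13 were above 0, and 8 were higher adjusted over the list alone against 1 over all genes tested. Among them HSP90AB1, a cytosolic chaperone, was at 303 ± 3.85 FPKM with BSA and 353 ± 12.1 with glucose (list adjusted p = 0.0147 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 23 were above 0, with 5 higher adjusted over the list alone and 0 over all genes. They included the nucleolar protein NOP56 at 19.1 ± 0.544 and 23.1 ± 0.259 and the spermidine synthase SRM at 28.7 ± 1.16 and 37.7 ± 2.79 (adjusted p = 0.00303 with an estimated correlation). Of 24 cholesterol synthesis genes 23 were above 0 with a median fold of 1.14, and ACAT2 was the member that passed either adjustment (adjusted p = 0.00303 with an estimated correlation). FDPS, farnesyl diphosphate synthase, was at 53.2 ± 2.15 and 61.1 ± 3.02 FPKM (SD, n = 3).

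Interferon-responsive, retinoic acid-responsive and monocyte genes fell as groups with glucose. When glucose was added to AGEs the interferon list fell too, while the retinoic acid and monocyte lists were not called. For the retinoic acid and monocyte lists, glucose cannot be told apart from the missing BSA. Of 24 type I interferon genes 22 were below 0, and 5 were lower adjusted over the list alone and 0 over all genes tested. They included the antiviral synthetases OAS3 at 10.7 ± 0.57 FPKM with BSA and 7.86 ± 0.492 with glucose and OAS1 at 3.79 ± 0.122 and 2.83 ± 0.0801 (list adjusted p = 0.0147 with an estimated correlation). All 9 retinoic acid response genes were below 0, with 5 lower adjusted over the list alone and 0 over all genes, such as the surface enzyme CD38 at 47.1 ± 2.63 and 39.0 ± 0.478 (adjusted p = 0.0147 with an estimated correlation). Of 9 monocyte and macrophage genes 8 were below 0. CSF1R, the receptor of macrophage colony-stimulating factor, was lower adjusted over the list alone, at 9.74 ± 1 and 6.66 ± 0.446 (SD, n = 3; list adjusted p = 0.0417 with an estimated correlation). Without AGEs 1 and glucose 3, the cholesterol and MYC lists had adjusted p = 0.0235 with an estimated correlation. The heat shock, interferon, retinoic acid and monocyte lists lost their calls, at adjusted p = 0.124, 0.0826, 0.0826 and 0.145 with an estimated correlation. Their library means (log2 deviation) did not overlap between BSA and glucose. They ran from -0.12 to -0.00 and 0.08 to 0.11 for heat shock, and 0.07 to 0.09 and -0.16 to -0.07 for interferon. For retinoic acid they ran from 0.06 to 0.13 and -0.25 to -0.10, and for monocyte genes from 0.04 to 0.15 and -0.18 to -0.04. These lists were chosen because they were called in the same libraries, so this lack of overlap is no separate support. Of all genes tested, 17% did not overlap between these groups, against 10% by chance. The lost calls alone do not show that glucose 3 carried these lists, and the ranges, which include glucose 3, do not decide it.

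A further set of lists passed with camera's preset correlation and not with an estimated one. Neutrophil receptors were lower in 16 of 24, 4 of them adjusted over the list alone. They included the granulocyte colony-stimulating factor receptor CSF3R at 17.8 ± 0.49 FPKM with BSA and 13.2 ± 0.523 with glucose (list adjusted p = 0.0748 with an estimated correlation). Cytokines were lower in 17 of 19, with IL1B at 9.56 ± 1.07 and 6.74 ± 1.09 and TNF at 33.2 ± 0.0695 and 28.2 ± 1.99 lower adjusted over the list alone (list adjusted p = 0.119 with an estimated correlation). NF-kappaB targets were lower in 16 of 19, with ICAM1 at 54.1 ± 1.88 and 42.4 ± 0.966, and immediate-early genes in 13 of 17, with EGR1 at 6.61 ± 0.359 and 4.97 ± 0.727 (SD, n = 3; adjusted p = 0.0667 for either list with an estimated correlation). In each, 4 members passed adjusted over the list alone. HIF1 targets were lower in 13 of 16 (adjusted p = 0.116 with an estimated correlation) and glucose transporters in 6 of 6 (adjusted p = 0.119 with an estimated correlation). SLC2A3, a member of either list, was lower adjusted over the list alone in both, and NDRG1 in the first. Oxidative phosphorylation genes were higher in 34 of 36 (adjusted p = 0.119 with an estimated correlation), cytosolic ribosomal proteins in 36 of 37 and antioxidant enzymes in 13 of 16 (adjusted p = 0.176 for either list with an estimated correlation). ATF4 targets were higher in 12 of 20 (adjusted p = 0.176 with an estimated correlation) and proliferation genes in 25 of 33 (adjusted p = 0.0969 with an estimated correlation). None of these lists had a member past the threshold over all genes tested. Without glucose 3 the preset calls were lost for neutrophil receptors (adjusted p = 0.126), cytokines (0.0611), HIF1 targets (0.139), ATF4 targets (0.109) and proliferation genes (0.0683). The mean log2 difference then went from -0.18 to -0.09 for cytokines, from 0.07 to 0.04 for proliferation and, with its call kept, from -0.13 to -0.07 for immediate-early genes. It moved little for neutrophil receptors (-0.10 to -0.08), HIF1 targets (-0.11 to -0.12) and ATF4 targets (0.07 in either fit). It grew, with calls kept, for antioxidant enzymes (0.11 to 0.17) and ribosomal proteins (0.07 to 0.11). Preset calls also failed in 3 of 12 fits with 1 library left out for antioxidant enzymes, in 4 for HIF1 targets and in 7 for ATF4 targets. NF-kappaB, transporter, oxidative phosphorylation, ribosomal and immediate-early lists kept theirs in 12 of 12. The transporter list had only 6 measured members, and its member SLC2A14 lay near the floor.

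Among the genes always named, TXNIP, a glucose-responsive arrestin, stood at 224 ± 8.78 FPKM with BSA and 188 ± 4.73 with glucose, and MPO at 110 ± 6.69 and 90.9 ± 1.2 (SD, n = 3). The limma adjusted p-values were 0.138 and 0.309 over all genes tested. AGER was at 1.65 ± 0.0925 and 1.15 ± 0.165 FPKM (adjusted p = 0.296), and ARRDC4, a paralog of TXNIP, at 5.62 ± 0.318 and 5.35 ± 0.613 (adjusted p = 0.864). With 1 library left out, TDG and CYP17A1 were called in 12 of 12 fits and BMF in 9 (not without BSA 2, glucose 1 or glucose 2). The other 7 genes were called in 1 to 4, and none of them without BSA 2, glucose 1 or any library of AGEs+glucose. In the fit of these 2 groups alone, only TDG and CYP17A1 of the 10 were called, with 5 higher and 0 lower calls. Quantile normalization gave 2 higher and 5 lower calls. Library weights gave 43 higher and 84 lower, the fit without AGEs 1 and glucose 3 gave 24 and 49, and removal of GC and length trends gave 12 and 28, so the balance of the 10 calls did not hold in these fits.

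**Figure D1:**
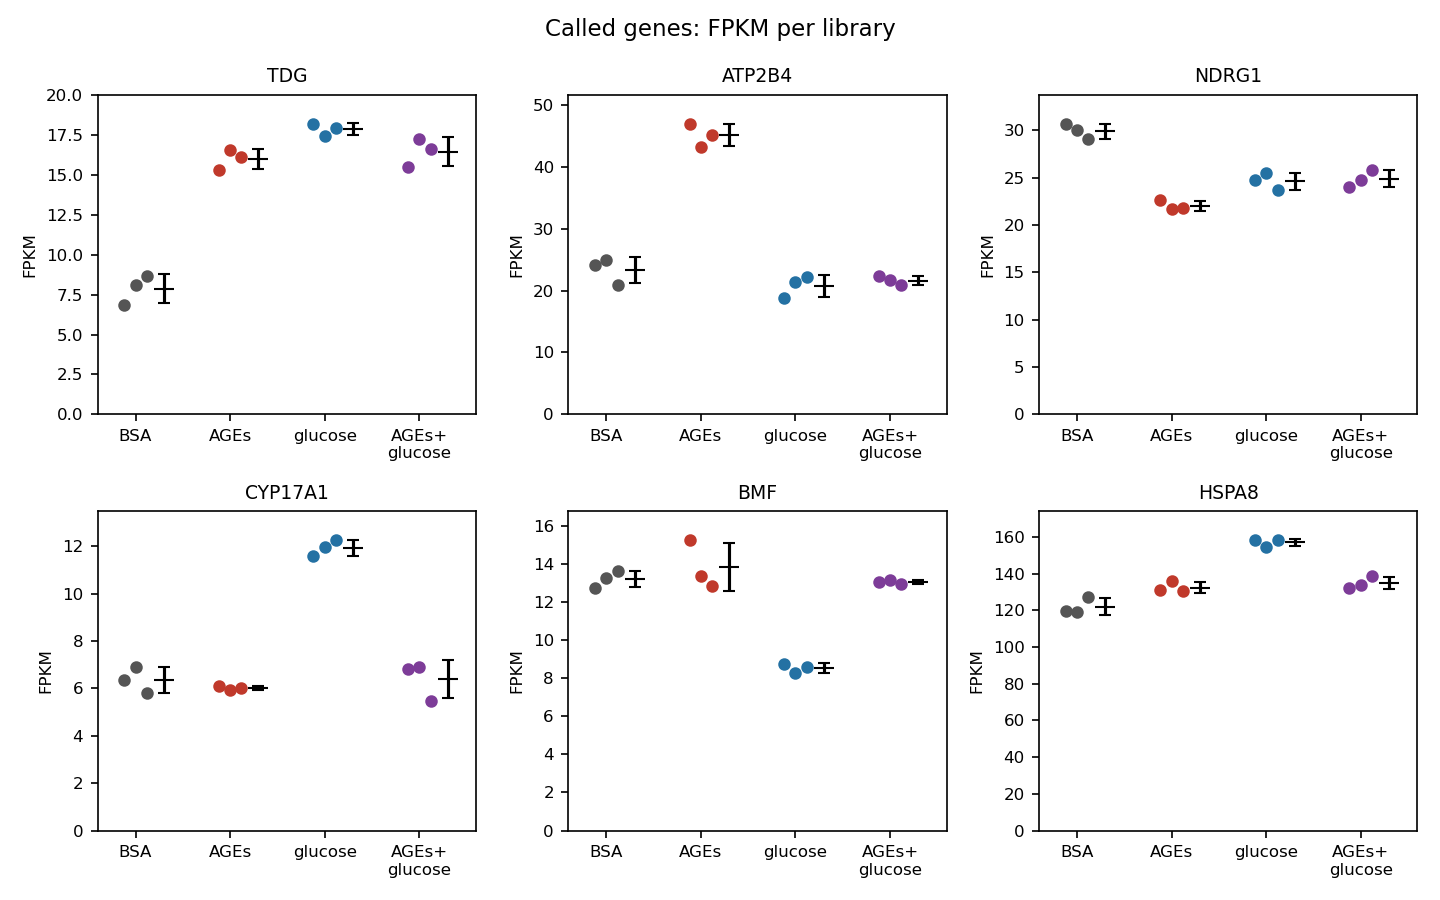
FPKM (y axis, from 0) of 6 called genes in each library of the 4 groups (x axis); each point is 1 library, and the bar beside them is the mean ± SD of 3 libraries. TDG lies lowest in BSA (mean 7.89), ATP2B4 highest with AGEs (45.1), and CYP17A1 highest (11.9) and BMF lowest (8.55) with glucose alone.

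The third comparison set AGEs with glucose against BSA. TDG rose to 16.5 ± 0.891 FPKM (SD, n = 3; log2 fold change 0.98 ± 0.08 SE, adjusted p = 0.000917). It was the only call by limma among 9751 genes, with 534 at an unadjusted p under 0.05 against 488 expected. Cholesterol synthesis genes rose as a group, with 22 of 24 above 0 and a median fold of 1.11. ACAT2, FDFT1, FDPS and NSDHL were higher adjusted over the list alone and 0 over all genes tested (list adjusted p = 0.00748 with an estimated correlation). FDFT1, squalene synthase, stood at 32.8 ± 0.692 FPKM with BSA and 38.6 ± 2.26 with both agents. Eosinophil and basophil genes also rose as a group, with 9 of 11 above 0 and 4 higher adjusted over the list alone (0 over all genes). They included the eosinophil peroxidase EPX at 12.1 ± 0.484 and 16.9 ± 0.678 FPKM and CLC at 2199 ± 117 and 2535 ± 30.5 FPKM (SD, n = 3; list adjusted p = 0.0399 with an estimated correlation). Leaving out AGEs 1 and glucose 3, these lists had adjusted p = 0.0295 and 0.113 with an estimated correlation. With GC and length trends removed they had 0.00422 and 0.0585, so the eosinophil list lost its call in either fit.

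The remaining lists past camera's threshold here were lost with an estimated correlation. All 19 cytokine and chemokine genes were below 0 (adjusted p = 0.236 with an estimated correlation). Interferon genes were below 0 in 21 of 24 (adjusted p = 0.0924 with an estimated correlation), NF-kappaB targets in 14 of 19 (adjusted p = 0.103 with an estimated correlation) and immediate-early genes in 12 of 17 (adjusted p = 0.117 with an estimated correlation). HIF1 targets were below 0 in 13 of 16 and glucose transporters in 5 of 6 (adjusted p = 0.0961 for either list with an estimated correlation). Oxidative phosphorylation genes were above 0 in 32 of 36 (adjusted p = 0.173 with an estimated correlation), and ribosomal proteins in 29 of 37 and antioxidant enzymes in 11 of 16 (adjusted p = 0.232 for either list with an estimated correlation). Adjusted over the list alone, the lower members were ICAM1, TNFAIP3 and BCL3 of the NF-kappaB targets, EGR1 and EGR3 of the immediate-early genes, NDRG1 of the HIF1 targets and SLC2A3 and SLC2A14 of the transporters. None passed over all genes tested. With 1 library left out, preset calls failed for HIF1 targets and immediate-early genes without BSA 3 (adjusted p = 0.0855 and 0.0582) and for antioxidant enzymes in 4 of 12 fits, and the other 6 lists kept theirs. Genes with the smallest p short of the threshold all had adjusted p = 0.646. BTG2, an antiproliferative gene, was at 69.0 ± 3.44 FPKM with BSA and 56.0 ± 0.345 with both agents, ARMC5 at 3.6 ± 0.152 and 1.93 ± 0.269, and THBS1 at 12.2 ± 0.592 and 8.9 ± 0.124 (SD, n = 3). In the other direction were the acetyltransferase-like gene NAT14, at 0.977 ± 0.0818 and 1.78 ± 0.119, and the glycine methyltransferase GNMT, at 1.93 ± 0.276 and 3.21 ± 0.424. MPO was at 126 ± 1.57 FPKM and TXNIP at 208 ± 3.98 with both agents (adjusted p = 0.892 for either). AGER was at 1.78 ± 0.0277 and ARRDC4 at 4.96 ± 0.189 FPKM. TDG was called in 12 of 12 fits with 1 library left out, and not in the fit of these 2 groups alone.

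**Figure D2:**
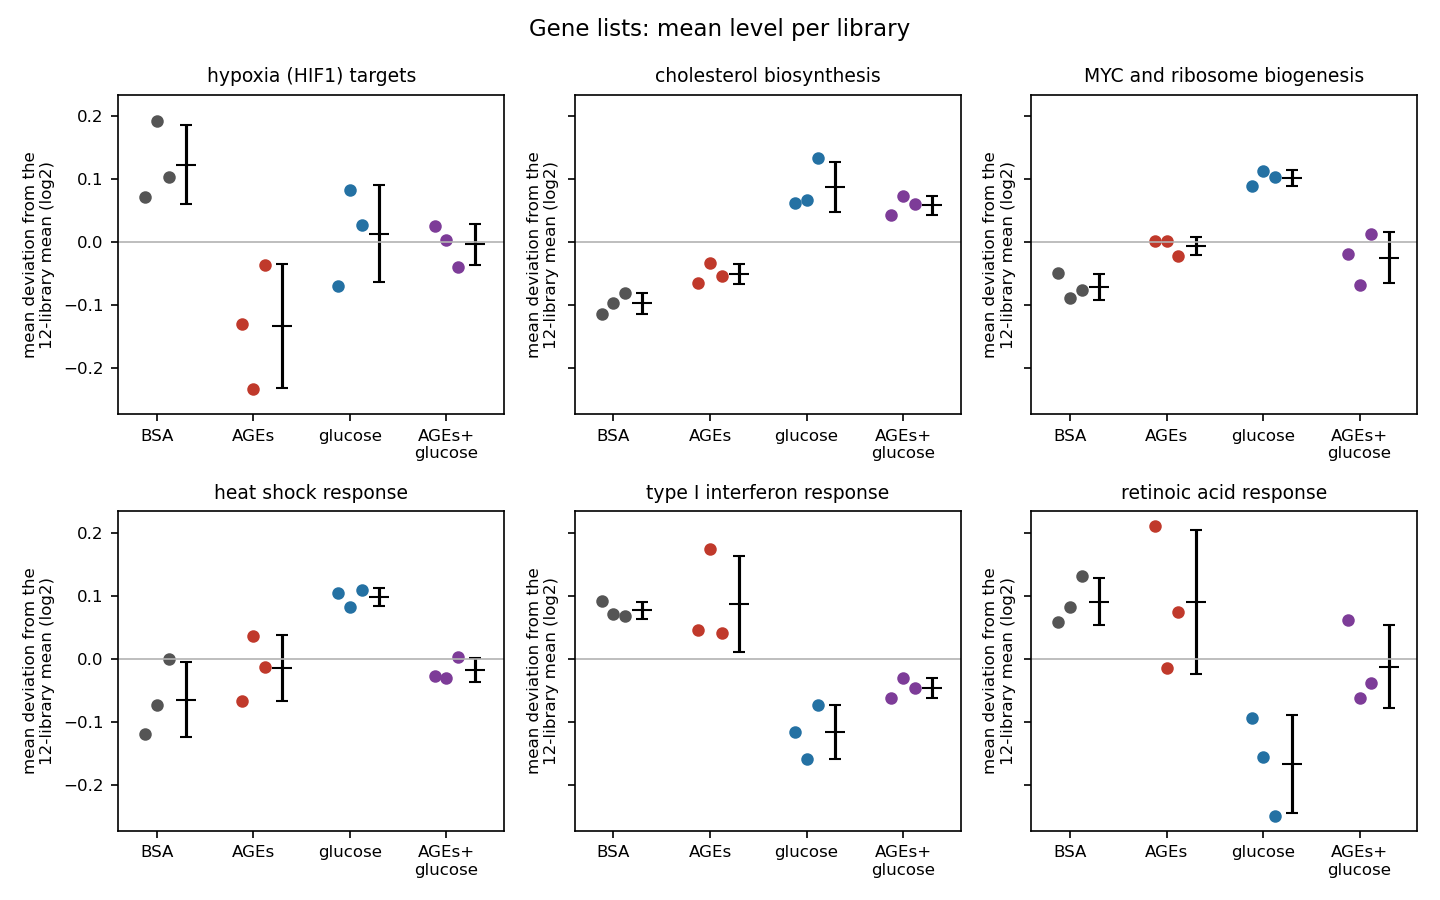
Mean deviation of a list's genes from their 12-library mean (y axis, log2) in each library of the 4 groups (x axis), for 6 lists; points are libraries and the bar beside them is the mean ± SD of 3 libraries. HIF1 targets average 0.12 in BSA and -0.13 with AGEs, while cholesterol synthesis genes average -0.10 in BSA, 0.09 with glucose and 0.06 with both agents.

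AGEs and glucose were then compared directly. The glucose group is not labelled as holding BSA or AGEs, so differences here may also hold a lack of added protein. ATP2B4 was higher with AGEs (45.1 ± 1.82 against 20.8 ± 1.8 FPKM, adjusted p = 0.000368). So were BMF (13.8 ± 1.26 against 8.55 ± 0.258, adjusted p = 0.00543) and CD300E (3.87 ± 0.27 against 2.13 ± 0.126, adjusted p = 0.017), a surface receptor of the CD300 family. CYP17A1 was lower with AGEs (6.02 ± 0.0936 against 11.9 ± 0.335 FPKM, SD, n = 3; adjusted p = 0.00323). These were the 4 limma calls, and CD300E was called in 7 of 12 fits with 1 library left out (not without AGEs 1, AGEs 2 or any glucose library). The fit of these 2 groups alone gave 1 higher and 5 lower calls in place of 3 and 1, without CD300E and BMF. TTC3, a ubiquitin ligase, at 3.7 ± 0.422 FPKM with AGEs and 5.38 ± 0.0984 with glucose, and MDFIC, a transcription regulator, at 2.06 ± 0.0547 and 6.04 ± 0.684, had the next smallest p among lower genes (adjusted p = 0.145 and 0.165). As groups, HIF1 targets (14 of 16 below 0), MYC and ribosome biogenesis genes (21 of 24), cholesterol synthesis genes (21 of 24) and heat shock genes (13 of 17) were lower with AGEs than with glucose. Interferon genes (21 of 24 above 0) and retinoic acid response genes (9 of 9) were higher. Adjusted over the list alone, 0, 0, 1 and 4 members of the lower lists and 7 and 3 of the higher lists passed, and 0 over all genes tested. Adjusted p was 0.0161 for each and 0.0476 for heat shock with an estimated correlation. For heat shock it was 0.133 without AGEs 1 and glucose 3. Without AGEs 2 the mean log2 difference of HIF1 targets went from -0.15 to -0.10, with the preset call kept.

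The remaining calls of camera between AGEs and glucose held only with the preset correlation. They were, higher with AGEs, neutrophil receptors (18 of 24 above 0, adjusted p = 0.0773 with an estimated correlation), monocyte genes (7 of 9, adjusted p = 0.0645 with an estimated correlation), and secondary and tertiary granule proteins (6 of 9, adjusted p = 0.151 with an estimated correlation). Adjusted over the list alone 4, 3 and 2 of their members passed. Also higher were NF-kappaB targets (14 of 19, adjusted p = 0.199 with an estimated correlation) and immediate-early genes (15 of 17, adjusted p = 0.167 with an estimated correlation), with 1 and 0 such members. Oxidative phosphorylation genes were lower with AGEs (27 of 36 below 0, adjusted p = 0.415 with an estimated correlation). Each of the 6 lost its preset call in some fit with 1 library left out. Without glucose 3 the adjusted p was 0.259 for granule proteins, 0.104 for neutrophil receptors, 0.178 for immediate-early genes and 0.0526 for NF-kappaB targets. Monocyte genes were lost without AGEs 2 (0.0824), NF-kappaB targets in 6 of 12 fits and oxidative phosphorylation in 3. Across genes, the log2 fold changes of AGEs and of glucose against BSA correlated at 0.46, where unchanged groups sharing the same BSA libraries gave 0.50 on average over 100 simulations (0.45 to 0.57). The covariance was 0.0146 against 0.0150 simulated. The simulation drew genes independently, for 3 libraries per group and with no outlying library. TDG was the 1 shared higher call, and 0 lower calls were shared. Independent lists would share 0.0010 higher calls, a value that leaves out the shared BSA libraries, in which TDG was lowest, so no excess is read from it. The 3 BSA libraries could not be split into parts of at least 2, so what they alone add to this correlation was not measured.

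Adding glucose to AGEs lowered ATP2B4 from 45.1 ± 1.82 to 21.6 ± 0.707 FPKM (SD, n = 3; log2 fold change -1.03 ± 0.08 SE, limma adjusted p = 0.000652). It was the only call of 9751 genes, with 363 at an unadjusted p under 0.05. ATP2B4 ran from 20.9 to 24.9 FPKM with BSA, from 18.7 to 22.2 with glucose and from 20.9 to 22.3 with both agents. It thus stood apart only in the libraries with AGEs alone. Its calls for AGEs against BSA, against glucose and here rest on those same libraries and are not separate results. Cholesterol synthesis genes (19 of 24 above 0) and HIF1 targets (14 of 16) rose as groups, each with adjusted p = 0.0253 with an estimated correlation, and interferon genes fell (22 of 24 below 0, adjusted p = 0.0387 with an estimated correlation). No member of these lists passed adjusted over the list alone. PFKFB4 stood at 8.97 ± 0.989 FPKM with AGEs and 11 ± 0.216 with both agents. Genes next in p were C8orf82, at 4.87 ± 0.786 and 2.71 ± 0.203, ARMC5, at 3.32 ± 0.328 and 1.93 ± 0.269, and, in the other direction, TTC3, at 3.7 ± 0.422 and 5.38 ± 0.173 (SD, n = 3; adjusted p = 0.156, 0.984 and 0.406). The zinc finger gene ZKSCAN8, at 6 ± 1.94 and 10.1 ± 0.316, and the Golgi protein gene GORASP2, at 6.62 ± 1.07 and 11.1 ± 1.44, followed (adjusted p = 0.984 for either). The interferon list without AGEs 1 and glucose 3 had adjusted p = 0.051 with an estimated correlation. With the preset correlation only, eosinophil and basophil genes (9 of 11 above 0, adjusted p = 0.0885 with an estimated correlation), oxidative phosphorylation genes (29 of 36, adjusted p = 0.751 with an estimated correlation), and mitochondrially encoded genes (12 of 13, adjusted p = 0.37 with an estimated correlation) passed upward. Immediate-early genes passed downward (14 of 17 below 0, adjusted p = 0.335 with an estimated correlation). Of these 4 lists mitochondrially encoded genes kept the preset call in 12 of 12 fits with 1 library left out, eosinophil genes in 10, oxidative phosphorylation in 8 and immediate-early genes in 4. Without AGEs 2 the HIF1 list kept its call while its mean log2 difference went from 0.13 to 0.08.

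Adding AGEs to glucose lowered CYP17A1 from 11.9 ± 0.335 to 6.41 ± 0.807 FPKM (adjusted p = 0.015). It raised BMF from 8.55 ± 0.258 to 13.1 ± 0.0979 (adjusted p = 0.0267) and LMO2, a haematopoietic transcription cofactor, from 10.7 ± 0.553 to 15.4 ± 0.342 (SD, n = 3; adjusted p = 0.0498). CYP17A1 ran from 5.80 to 6.91 FPKM with BSA and from 5.93 to 6.11 with AGEs, and BMF from 12.8 to 13.6 and from 12.9 to 15.3. Both genes thus stood apart only with glucose alone, the group not labelled as holding BSA or AGEs. For them an effect of AGEs here, or of glucose against BSA, cannot be told apart from a lack of added protein. Since the glucose group is the reference, every other result of this contrast may likewise hold the addition of protein. Heat shock genes averaged -0.07, -0.02, 0.10 and -0.02 (log2 deviation) with BSA, AGEs, glucose and both agents. MYC and ribosome biogenesis genes averaged -0.07, -0.01, 0.10 and -0.02 in that order. MYC and ribosome biogenesis genes fell as a group (22 of 24 below 0, adjusted p = 0.0159 with an estimated correlation). Heat shock genes (15 of 17) and proliferation genes (29 of 33) fell, and eosinophil and basophil genes (9 of 11 above 0) and retinoic acid response genes (8 of 9) rose, each with adjusted p = 0.0467 with an estimated correlation. Adjusted over the list alone 0, 3, 4, 1 and 0 members of these lists passed, in that order, and 0 over all genes tested. HSPA8 stood at 157 ± 2 FPKM with glucose and 135 ± 3.36 with both agents, MCM4, a replicative helicase subunit, at 22.3 ± 0.137 and 18.3 ± 0.4, and MPO at 90.9 ± 1.2 and 126 ± 1.57 (SD, n = 3; adjusted p = 0.317, 0.314 and 0.12). With library weights HSPA8, MCM4 and MPO were called. MPO was also called with GC and length trends removed and in the fit of these 2 groups alone. It was called as well without AGEs 1, and without AGEs 1 and glucose 3, and in no other fit. Among the smallest p short of the threshold, CD300E was at 2.13 ± 0.126 and 3.55 ± 0.249, the selenoprotein gene SEP15 at 49.9 ± 3.29 and 19.3 ± 5.84 and the cyclin CCNE2 at 3.46 ± 0.263 and 2.42 ± 0.135 (adjusted p = 0.0795, 0.212 and 0.313). Without AGEs 1 and glucose 3 the MYC list had adjusted p = 0.0418 with an estimated correlation. The heat shock, proliferation, eosinophil and retinoic acid lists lost their calls (adjusted p = 0.128, 0.0982, 0.128 and 0.106 with an estimated correlation). With GC and length trends removed the proliferation, eosinophil and retinoic acid lists also lost theirs (adjusted p = 0.113, 0.0694 and 0.0571 with an estimated correlation). With the preset correlation only, primary granule proteins passed upward (14 of 19, MPO adjusted over the list alone, adjusted p = 0.117 with an estimated correlation). So did NADPH oxidase genes (12 of 14, adjusted p = 0.11 with an estimated correlation), neutrophil receptors (17 of 24, 3 of them adjusted over the list alone, adjusted p = 0.0632 with an estimated correlation) and interferon genes (14 of 24, adjusted p = 0.266 with an estimated correlation). ATF4 targets passed downward (13 of 20, adjusted p = 0.246 with an estimated correlation). Without glucose 3 the preset call of primary granule proteins was lost (adjusted p = 0.309) and their mean log2 difference went from 0.13 to 0.07. That of proliferation genes went from -0.09 to -0.06, with the preset call kept. With 1 library left out, the preset call held for neutrophil receptors in 12 of 12 fits, for ATF4 targets in 8, for NADPH oxidase genes in 7 and for interferon genes in 5. With 1 library left out, CYP17A1 was called in 11 of 12 fits (not without glucose 3), BMF in 2 (without AGEs 1 and without AGEs 3) and LMO2 in 1 (without AGEs 1). CYP17A1 and LMO2 were not called in the fit of these 2 groups alone, which gave 2 higher and 3 lower calls. Quantile normalization gave 1 higher and 1 lower call. Library weights gave 22 and 5, the fit without AGEs 1 and glucose 3 gave 9 and 1, removal of GC and length trends 7 and 1, and the fit without AGEs+glucose 2 gave 0 and 4.

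The interaction asked whether the joint change differed from the sum of the separate changes on the log2 scale. The glucose group is not labelled as holding BSA, so that sum may also hold the loss of BSA. TDG was below that sum, with an interaction of -1.05 ± 0.11 SE (limma adjusted p = 0.0148). It stood at 16 ± 0.647 FPKM with AGEs, 17.9 ± 0.371 with glucose and 16.5 ± 0.891 with both (SD, n = 3). With BSA it ran from 6.86 to 8.66 FPKM, so TDG was low in the BSA libraries alone. Its rises against BSA and this interaction rest on those same libraries and are not separate results. In the stimulated groups TDG ran from 15.3 to 18.2 FPKM, and it was not called between any of them. What set the BSA libraries apart for TDG was not tested. HIF1 targets lay above the sum (14 of 16, 3 adjusted over the list alone, adjusted p = 0.0107 with an estimated correlation). MYC and ribosome biogenesis genes (22 of 24, 6 adjusted over the list alone, adjusted p = 0.00693 with an estimated correlation) and heat shock genes (16 of 17, HSPA8 adjusted over the list alone, adjusted p = 0.0325 with an estimated correlation) lay below it. No member passed over all genes tested. In fits without AGEs 1 and glucose 3 the HIF1, MYC and heat shock lists had adjusted p = 0.101, 0.0581 and 0.15 with an estimated correlation. With the preset correlation each kept its call in 12 of 12 fits with 1 library left out. The lost calls alone do not show that AGEs 1 and glucose 3 made these interactions. ATP2B4, STOML2, GORASP2, FAM134A and NDRG1 had the smallest p short of the threshold (log2 interaction -0.87, -0.73, 1.35, 0.98 and 0.44, adjusted p = 0.0555, 0.116, 0.094, 0.116 and 0.223). TDG was called in 8 of 12 fits with 1 library left out, and not without BSA 2, AGEs 3, glucose 2 or AGEs+glucose 3. With library weights the interaction had 9 calls above and 5 below the sum, and without AGEs 1 and glucose 3 it had 4 and 3.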

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

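All tests of explanations in this part were written after the results they measure had been seen. The interaction contrast marked TDG and 11 gene lists as differing between the change from BSA to glucose and the change from AGEs to AGEs with glucose. The glucose group is not labelled as holding BSA. The first change may therefore also hold the loss of BSA, which cannot be told apart from glucose in this contrast. TDG had a log2 interaction of -1.05, and was low in the BSA libraries alone. The mean log2 interaction was 0.24 for HIF1 targets, -0.19 for MYC and ribosome biogenesis, -0.17 for heat shock, 0.15 for the retinoic acid response, 0.13 for cytokines and chemokines, 0.12 for mitochondrially encoded genes and -0.12 for proliferation. It was 0.10 for neutrophil receptors, -0.10 for oxidative phosphorylation, -0.09 for ATF4 targets and -0.06 for cytosolic ribosomal proteins. With an estimated correlation the HIF1, MYC and heat shock lists remained past the threshold, and without AGEs 1 and glucose 3 none of the 3 did. Each of the 3 kept its preset call in 12 of 12 fits with 1 library left out. The others were lost, at adjusted p = 0.152 with an estimated correlation for the retinoic acid response and neutrophil receptors, 0.325 for cytokines, 0.0686 for proliferation and 0.272 for ATF4 targets. It was 0.375 for mitochondrially encoded genes, oxidative phosphorylation and ribosomal proteins. Of these 8, proliferation kept its preset call in 12 of 12 fits with 1 library left out. Without glucose 3 the preset adjusted p was 0.224 for cytokines, 0.294 for mitochondrially encoded genes, 0.138 for neutrophil receptors, and 0.106 for the retinoic acid response and for ATF4 targets. The mean log2 interaction was then 0.04 for cytokines and for mitochondrially encoded genes. It was 0.07 for neutrophil receptors, 0.11 for the retinoic acid response and -0.09 for ATF4 targets. It grew to -0.17 for oxidative phosphorylation and -0.10 for ribosomal proteins. These last were -0.05 without AGEs 2 and -0.03 without BSA 2, respectively.

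HIF1 targets were lower with AGEs. GC content and length trends are argued against as the whole cause by adjusted p = 0.00213 with an estimated correlation after their removal. AGEs 1 is argued against by adjusted p = 0.0227 without it and glucose 3. That the BSA libraries alone stand apart stays open. The list was lower with AGEs than with glucose and than with both agents by camera (larger adjusted p = 0.0253 with an estimated correlation). Between library means the groups overlapped (gap -0.034 log2 to glucose and -0.004 to both agents): AGEs ran from -0.23 to -0.04, glucose from -0.07 to 0.08 and both agents from -0.04 to 0.03 (mean log2 deviation). Culture density and oxygen at harvest were not tested.

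Heat shock, MYC and cholesterol lists were higher with glucose. GC content and length trends are argued against by a largest adjusted p of 0.0112 with an estimated correlation after their removal. For glucose 3, the lower of glucose 1 and 2 lay above the highest BSA library by at least 0.083 log2 in each list, more than the SD of the BSA libraries; this gap was chosen knowing that the list test without AGEs 1 and glucose 3 gives adjusted p = 0.124 for heat shock, which leaves that list's call dependent on those libraries. A lack of BSA in the glucose culture would not raise the cholesterol list when glucose was added to AGEs, yet it rose (adjusted p = 0.0253 with an estimated correlation, with a gap of 0.076 log2 between the library means of the groups, against a larger SD of 0.016). For heat shock and MYC the same contrast had a smallest adjusted p of 0.827, so the missing BSA cannot be told apart from glucose there.

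Splits of the libraries into groups of the same sizes were counted for each contrast, the real one included. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the real count and the highest among the remaining splits are given. For genes these were 3 and 1 (AGEs against BSA), 10 and 3 (glucose against BSA), 1 and 3 (both agents against BSA), 4 and 1 (AGEs against glucose), 1 and 3 (both against AGEs) and 3 and 2 (both against glucose). For lists they were 8 and 2, 17 and 7, 11 and 2, 12 and 7, 7 and 1, and 10 and 6. For the interaction 39 of 100 splits, the real one included, gave at least as many genes as the real 1 (highest other 4), and 6 of 100, again with the real one, gave at least as many lists as the real 11 (highest other 15), so chance is not excluded for either.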

How the results depend on the processing

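Fits without AGEs 1 and glucose 3, with GC and length trends removed, and list tests with library weights, or with each library left out, were chosen after the data were seen. No named gene or list that was called changed sign, but the balance of higher and lower calls turned in several fits, as given below. Comparisons are given in the order AGEs, glucose and both agents against BSA, AGEs against glucose, both against AGEs, both against glucose, interaction. Library weights gave 10, 127, 5, 15, 2, 27 and 14 calls, of which 2, 43, 2, 9, 1, 22 and 9 were higher (the cause was not tested, but these weights are lowest for AGEs 1 and glucose 3). Without those libraries the counts were 9, 73, 4, 6, 6, 10 and 7 (4, 24, 3, 4, 3, 9 and 4 higher), and with GC and length trends removed 8, 40, 1, 13, 1, 8 and 3 (2, 12, 1, 9, 0, 7 and 0 higher). The main fit had 2, 5, 1, 3, 0, 2 and 0 higher among 3, 10, 1, 4, 1, 3 and 1. All main calls were among them, except CD300E in AGEs against glucose without the 2 libraries. Only the groups compared gave 7, 5, 0, 6, 1 and 5 calls (5, 5, 0, 1, 0 and 2 higher), for a cause not tested. This fit lost NDRG1 (AGEs against BSA), 8 of the 10 calls for glucose against BSA (all but TDG and CYP17A1), TDG (both against BSA), BMF and CD300E (AGEs against glucose) and LMO2 and CYP17A1 (both against glucose). A 2-fold minimum left 0, 1, 0, 1, 1, 0 and 1, by construction. No filter gave 2 calls for both against AGEs and 3 for the interaction, and a mean FPKM of at least 5 and TMM scaling each 2 for the interaction; the cause was not tested.

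With the replicate number as a block the calls were 2, 2, 1, 3, 1, 0 and 1, and the lists for AGEs against BSA 5. Same-numbered libraries deviated together with r from -0.21 to 0.13 (mean -0.02, against 0.01 for different numbers), and 3 of 12 libraries correlated best with their own number, so the numbers were not taken to pair the samples.

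Leaving out 1 library gave 2 to 6, 3 to 16, 1 to 3, 4 to 8, 1 to 4, 0 to 7 and 0 to 4 calls. For glucose against BSA there were 3 without BSA 2, glucose 1, AGEs+glucose 1 or AGEs+glucose 3, 5 without AGEs+glucose 2, 6 without BSA 1, glucose 2 or glucose 3, and 16 without AGEs 1. For AGEs against BSA there were 6 without AGEs 1, and for AGEs against glucose 8 without glucose 2. For both against BSA there were 2 without BSA 1, BSA 2, AGEs 1, glucose 3 or AGEs+glucose 1, and 3 without BSA 3. For both against AGEs there were 2 without BSA 3, AGEs 2 or glucose 3, 3 without AGEs 1 or AGEs+glucose 2, and 4 without AGEs+glucose 1. For both against glucose there were 0 without glucose 3, 1 without BSA 1, BSA 2, BSA 3, AGEs 2 or AGEs+glucose 3, and 7 without AGEs 1; without AGEs+glucose 2 there were 0 higher and 4 lower. The interaction had 0 without BSA 2, AGEs 3, glucose 2 or AGEs+glucose 3, 2 without AGEs 2, glucose 3 or AGEs+glucose 2, 3 without AGEs 1 or glucose 1, and 4 without AGEs+glucose 1. Lists with 1 library left out numbered 2 to 9 for AGEs against BSA (2 without BSA 2 or AGEs 2, 4 without BSA 3, AGEs 1 or AGEs 3, and 5 without BSA 1, AGEs+glucose 1 or AGEs+glucose 2), 4 to 8 for both against AGEs (4 without AGEs 3) and 7 to 13 for the interaction (7 without glucose 3). The lists that held with an estimated correlation were called by preset camera in 12 of 12 such fits. Of the 50 calls made with the preset correlation only, 36 were lost in at least 1 such fit, 24 of them without AGEs 1 or without glucose 3.

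Lists past the threshold fell from 8, 17, 11, 12, 7, 10 and 11 to 1, 6, 2, 6, 3, 5 and 3 with an estimated correlation; to 1, 2, 1, 6, 2, 1 and 0 with that and without AGEs 1 and glucose 3; and with that and the trends removed to 1 (AGEs), 7 (glucose), 2 (both; cholesterol synthesis and, in place of the eosinophil list, interferon at adjusted p = 0.0451), 3 (both against AGEs), 2 (both against glucose; MYC and heat shock) and 4 (interaction). Fry gave 3 for AGEs against BSA, 3 for both against AGEs and 6 for the interaction. For AGEs against BSA no filter, a mean of at least 5 and TMM scaling each gave 5 and quantile normalization 4. Without AGEs 1 and glucose 3, preset camera gave 17 for both against BSA. The correlation of AGEs and glucose fold changes, 0.46, was 0.55 without those 2 libraries and 0.34 (without AGEs 2) to 0.59 (without BSA 3) with 1 left out. The simulated mean of 0.50 was for 3 libraries per group and depends on group sizes, so these values cannot be set against it. Depth is unknown, so what it limits cannot be stated.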

Other observations

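Tests of explanations in this part were chosen after the results were seen. TXNIP, which glucose induces in many cell types through MondoA, was not higher in the glucose libraries: it stood at 224 ± 8.78 FPKM with BSA, 214 ± 7.07 with AGEs, 188 ± 4.73 with glucose and 208 ± 3.98 with both agents (SD, n = 3). With glucose it was lower adjusted over the list of 14 MondoA and ChREBP targets alone, as was ARRDC3, and not over all genes tested (limma adjusted p = 0.138); the list itself had adjusted p = 0.0796. TXNIP was called for glucose against BSA under quantile normalization, with library weights and with GC and length trends removed. Osmotic stress (NFAT5) targets, NRF2 targets and the NET formation list were not called for glucose (adjusted p = 0.639, 0.673 and 0.237). Library means of the NFAT5 list had an SD of 0.16 with BSA and 0.11 with glucose (log2), so its lack of a call says little. No group served as a control for the osmotic load of glucose. The NET formation list was tested without PADI4 and ELANE.

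Retinoic acid response genes and neutrophil receptors were lower with glucose (adjusted p = 0.0147 and 0.0748 with an estimated correlation). MYC and ribosome biogenesis genes were higher. Without AGEs 1 and glucose 3 the retinoic acid list had adjusted p = 0.0826 with an estimated correlation. A hypothesis is that the glucose cultures held more immature, dividing cells, which may then raise promyelocyte genes. That list was not called (adjusted p = 0.606 with camera's preset correlation, 8 of 14 above 0), which neither bears the hypothesis out nor excludes it. Its member MPO lay the other way, at 110 ± 6.69 FPKM with BSA and 90.9 ± 1.2 with glucose (SD, n = 3; adjusted p = 0.309 over all genes tested). Primary granule proteins, with 11 of 19 below 0, were not called either (adjusted p = 0.47). Proliferation genes lay above 0 in 25 of 33 (camera adjusted p = 0.00151, and 0.0969 with an estimated correlation). This list, proliferation and cell cycle, leaned on glucose 3, whose mean log2 deviation was 0.116 against 0.009 and 0.030 for glucose 1 and 2, and without glucose 3 it had adjusted p = 0.0683 with the preset correlation. The hypothesis stays open, and for the retinoic acid list the missing BSA cannot be told apart from glucose. For the retinoic acid list GC content and length trends are argued against as the whole cause by adjusted p = 0.0112 with an estimated correlation after their removal. For the list of neutrophil surface receptors and maturation that p was 0.0748 before the removal and 0.0545 after it. The list thus had no call to lose, and this test cannot decide on the trends. Without glucose 3 the list lost its preset call (adjusted p = 0.126), while its mean log2 difference went from -0.10 to -0.08.

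TDG had 1 named pseudogene and HSPA8 had 20 in the annotation used, and ACAT2 overlapped 2 coding genes and THBS1 1; with FPKM alone, reads shared between copies or neighbours were not separated, so the levels of these genes are uncertain to that extent. SLC2A14, a close paralog of SLC2A3, stood at 1.65 ± 0.898 FPKM with BSA, 0.324 ± 0.561 with AGEs, 0.7 ± 0.849 with glucose and 0.0341 ± 0.0296 with both agents (SD, n = 3). It was among the few measured members of the glucose transporter list, so these low and uneven values enter that list's mean differences.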
